A study of Mus musculus with 48 samples.

How the data were processed

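The series measured RNA from mouse lung with 3'-end sequencing libraries. RiboTag mice carry an HA-tagged ribosomal protein in a chosen cell type, and precipitation with an anti-HA antibody recovers the RNA bound to tagged ribosomes. Per the labels, 24 mice each gave an epithelial library and a whole lung library, 48 libraries in all, made with anti-HA immunoprecipitation and the Lexogen QuantSeq Forward kit. The labels give the same extraction protocol for both kinds of library. How the whole lung libraries differ from the epithelial ones in preparation, and whether they hold ribosome-bound RNA, is not given in the sources used here. Differences between the compartments may therefore include a difference in preparation.

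The authors deposited 1 table of read counts, whole numbers per Ensembl mouse gene and library with no normalization. It holds 42548 genes, of which 10826 had no count in any library. Per the submitters' processing notes, STAR 2.5.2b and the GRCm38 genome build were used, and the counting program and annotation release are not given in the sources used here. Each table column was matched to a sample through its name, which holds the mouse number and a letter for the compartment, read here as E for epithelium and I for whole lung. The column read as the whole lung library of 3G9 mouse 218 carries an unexplained suffix, and no column was left unused.

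The table names genes by Ensembl ID and does not pair them with symbols. The reference table of gene names used here (GRCm38.p6, 49997 genes) matched 0 of the 42548 IDs. The 26 lists of gene symbols fixed before the data were examined, which cover lung cell types and pathways, and the symbols in the rule for named genes could therefore not be applied, and the list tests were not run. Genes are described instead as groups that the data define. Single genes are given by ID, at most 2 higher and 2 lower per comparison, the first in the order of the rule for named genes. That rule took, per comparison, the 10 genes with the largest fold in each direction among those with an adjusted p under 0.05, a mean of at least 5 CPM (counts scaled to library size) in the higher arm and the same sign of the mean difference within every batch holding both arms. Where no gene passed, it took the 5 genes with the smallest p.

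Counts were analysed in R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, filterByExpr on arm, robust dispersions and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. All 4 arms of a compartment (24 libraries) shared a fit with terms for arm and batch, because the arms are spread unevenly over the 3 batches. The labels give the control treatment as Vehicle in S061 and S135 and as Axum8 in S151, and bleomycin control mice were kept as a single arm. The epithelial fit tested 17291 genes and the whole lung fit 19345. Epithelium was compared with whole lung in the 6 saline mice with the mouse as a block, since each mouse gave both libraries. The interaction of compartment with bleomycin was fitted in the 6 saline and 9 bleomycin control mice with the mouse as a block and a batch term per compartment. Standard errors of log2 fold changes were computed as the fold change divided by the root of the F statistic. Deviations of the 2 libraries of a mouse from their arm and batch means correlated with a median r of 0.168 across genes (range 0.073 to 0.445). Libraries of different mice were not compared in this way, so the value does not test the pairing. The pairing comes from the mouse numbers in the labels.

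To ask whether a treatment moved genes that bleomycin changed, gene sets were defined and tested in different mice, so that no control library entered both steps. For KIRA8 the sets came from bleomycin against saline in batch S151 and were tested in batches S061 and S135. For 3G9 they came from S135 and were tested in S151. The sets held genes with an adjusted p under 0.05, or the 100 of that direction with the smallest p where fewer than 20 passed. The test was fry in limma 3.58.1, which asks whether the genes of a set move on balance in 1 direction, with camera (preset correlation 0.01, and an estimated correlation) beside it.

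Further gene groups were defined after the data were examined. Genes at least 2-fold higher or lower in epithelial than in whole lung libraries of saline mice are called epithelium-enriched and epithelium-depleted. Where a comparison itself used saline mice, the groups came from the saline mice of the other batch. Batch-limited genes are the 146 genes with at least 50 CPM in each of the 12 libraries of batch S061 and a median under 0.5 CPM in the libraries of the other batches.

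Total counts ran from 7163613 to 51797377 per library. The lowest was the epithelial library of KIRA8 mouse 155 and the highest the whole lung library of bleomycin control mouse 45. A group with no count is given a floor of 3 counts summed over its libraries, and such floors cover counting error only, since reads of this kind of library are not independent molecules. No 2 libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 10.8 over 134 pairs).

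The scripts were tested on simulated counts with 200 genes changed, drawn from the real means, library sizes and dispersions. For KIRA8 against bleomycin control in epithelium, 42% of the 2-fold and 65% of the 4-fold changes were called over 16389 genes, with 6 unchanged genes called. For 3G9 in epithelium these were 31% and 65% over 16450 genes, with 3 unchanged genes called. For bleomycin against saline in epithelium they were 50% and 62% over 16558 genes, with 6 unchanged genes called, and for KIRA8 against 3G9 in epithelium 19% and 60%, with 4. In whole lung the 2-fold and 4-fold recoveries were 66% and 78% for bleomycin against saline, 61% and 71% for KIRA8, 48% and 72% for 3G9, and 27% and 75% for KIRA8 against 3G9, with 7, 8, 8 and 3 unchanged genes called. They were 48% and 86% for the compartments in saline mice, with 4 unchanged genes called, and 40% and 67% for the interaction, with 3. A simulated shift of -0.5 in 242 genes under KIRA8 was estimated at -0.489 by the set test, and an unchanged set at 0.0477.

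The alternatives tried were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test and limma voom with sample quality weights. Others were no low-count filter, a stricter filter (over 1 CPM in at least 4 libraries), no batch term and sex as a term. Further ones were a fit with the arms compared alone and fits within a batch. Each mouse of the arms compared was also left out in turn. Fits without batch S061, and with the share of batch-limited genes as a term, were added after seeing the data. Marker pairs of cell cycle phases came from scran 1.30.0, which lists them by Ensembl ID.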

Results

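Mice were given bleomycin, a drug used to injure the lung and cause fibrosis in mice, or saline, and part of the bleomycin mice received KIRA8, a small-molecule inhibitor of the stress sensor IRE1α, or 3G9, an antibody against the integrin αvβ6 that blocks activation of TGFβ. There were 6 saline mice, 9 bleomycin control mice, 5 bleomycin mice with KIRA8 and 4 with 3G9. Each mouse gave an epithelial and a whole lung library. The mice came in 3 batches. Batch S061 held 3 bleomycin control and 3 KIRA8 mice, S135 held 3 saline, 2 bleomycin control and 2 KIRA8 mice, and S151 held 3 saline, 4 bleomycin control and 4 mice with 3G9. Total counts per library ranged from 21790283 to 51797377 in S061, from 7163613 to 20468041 in S135 and from 24751240 to 36945995 in S151.

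Within each compartment, batch was the strongest division of the libraries. The first principal component held 52.6% of the variance of epithelial and 55.8% of that of whole lung libraries, and batch accounted for 99.3% and 99.0% of the spread along it. Genes higher in males, picked in the other mice, matched the label of sex in 48 of 48 libraries, while the female-linked gene did not follow the label in the 4 libraries of male-labelled mice of S061. A group of 146 genes, the batch-limited genes, made up 6.01% to 12.7% of counts in epithelial and 7.21% to 9.81% in whole lung libraries of S061. The female-linked gene is 1 of the 146. In the other batches the group held at most 0.0530% of an epithelial library, and at most 0.0438% of a whole lung library apart from bleomycin control mouse 149 of S135, at 0.846%.

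**Figure D1:**
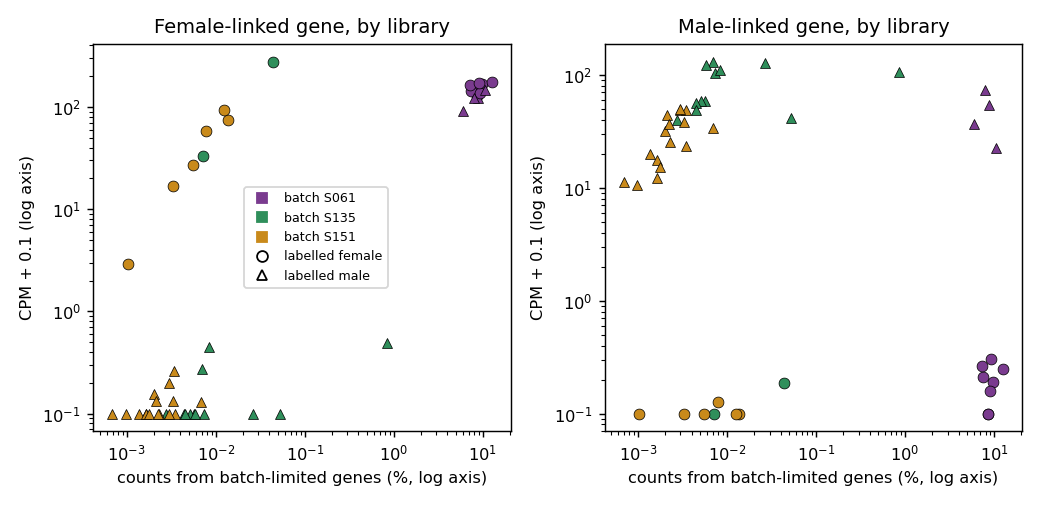
Level of the gene that best separated the sexes toward females in batches S135 and S151 (left) and toward males in all libraries (right), in CPM plus 0.1 on a log axis, against the percent of counts from the 146 batch-limited genes on a log axis, 1 point per library. The S061 libraries of male-labelled mice show 92.0 to 147 CPM of the female-linked gene, while those of other batches show at most 0.391 CPM.

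Saline mice showed how the epithelial and whole lung libraries differ, without naming the cells they hold. Of 14885 genes tested, 4059 were higher and 4506 lower in epithelial than in whole lung libraries of the same mice, and 1965 of the former and 3220 of the latter differed by at least 2-fold. The 10 genes with the largest enrichment lay between 2.91 and 3.41 on the log2 scale and the 10 with the largest depletion between -6.66 and -5.82. ENSMUSG00000064057 stood at 4509 ± 1747 CPM in epithelial and 413 ± 134 CPM in whole lung libraries (SD, n = 6 mice). ENSMUSG00000085396 stood at 0.411 ± 0.465 CPM in epithelial and 40.8 ± 34.6 CPM in whole lung libraries (SD, n = 6 mice). Adjusted p was 8.12e-08 for the first and 2.11e-07 for the second. The 1340 genes depleted at least 8-fold held 0.288% ± 0.0645 (SD, n = 3) of counts in epithelial libraries of saline mice in S151 and 0.558% ± 0.124 (SD, n = 3) in S135, against 8.75% ± 1.24 and 15.6% ± 0.620 in whole lung libraries of the same mice. In epithelial libraries of S061, which held no saline mice, the same genes made up 6.46% ± 1.26 in bleomycin control and 8.73% ± 1.46 in KIRA8 mice (SD, n = 3 each), and in whole lung libraries 12.6% ± 0.391 and 13.2% ± 0.731. Over the epithelial libraries of S061 this share rose with that of the batch-limited genes. It ran from 5.02% beside 6.01% in bleomycin control mouse 45 to 10.3% beside 12.7% in KIRA8 mouse 20. Its differences from other batches and between these arms therefore cannot be told apart from the batch-limited RNA.

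Bleomycin against saline asked how the injury changed RNA in each compartment. In epithelium, 787 genes were higher and 721 lower after bleomycin, 8.72% of those tested, with a median size of 0.86 on the log2 scale among the called genes, and 657 changed by over 2-fold. The largest rise by the rule was that of ENSMUSG00000029377, from 2 counts over the 6 saline libraries to 3.39 ± 1.97 CPM (SD, n = 6) in the bleomycin control libraries of S135 and S151, the batches with saline mice, with differences of 5.01 within S135 and 6.38 within S151 on the log2 scale (adjusted p = 4.52e-07). The next, ENSMUSG00000028307, is a batch-limited gene: it reached 828 ± 1266 CPM (SD, n = 9) because of S061, its difference was 5.03 in S135 and 0.17 in S151, and it fell to a log2 fold change of 0.57 and lost its call without mouse 149. In the same batches ENSMUSG00000005547 went from 330 ± 205 CPM (SD, n = 6) to 80.7 ± 44.9 CPM (SD, n = 6), a log2 fold change of -1.95 ± 0.39 (SE, adjusted p = 0.00307). ENSMUSG00000030048 went from 8.38 ± 4.40 CPM (SD, n = 6) to 2.29 ± 1.73 CPM (SD, n = 6), a log2 fold change of -1.88 ± 0.43 (SE, adjusted p = 0.00558).

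Among epithelium-depleted genes called in epithelial libraries after bleomycin, most were higher, as were most called genes of the same fits (262 of 321 in S151 and 143 of 213 in S135). With the group taken from saline mice of S135 and tested in S151, 51 of its 2337 members were higher and 2 lower, with a median log2 fold change of 0.15. In the reverse arrangement 31 of 2693 were higher and 4 lower, with a median of 0.10. The set tests of these 2 groups did not pass after adjustment over 32 tests (fry adjusted p = 0.715 for both, camera adjusted p = 0.0553 and 0.221, and adjusted p = 0.913 for both with an estimated correlation). Epithelium-enriched genes had medians of -0.11 in S151, with 12 of 1575 higher and 21 lower, and 0.05 in S135, with 27 of 2029 higher and 24 lower. The first passed camera (adjusted p = 0.000569) but not with an estimated correlation (adjusted p = 0.787).

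In whole lung, 1162 genes were higher and 800 lower after bleomycin, 10.1% of those tested, with a median size of 0.657 on the log2 scale among the called genes. Of the 10 genes with the largest rise by the rule, 9 were batch-limited genes, and 32 of the 146 batch-limited genes were called higher in all. ENSMUSG00000022875, of that group, had no count in the 6 saline libraries and stood at 16.1 CPM in the bleomycin control libraries of S135 and S151, at least 816-fold higher against a floor of 3 counts over the saline libraries. ENSMUSG00000066071, outside the group, also had no count in saline libraries and stood at 13.3 CPM, at least 676-fold higher. Both rises came mainly from mouse 149: the differences within S151 were 2.05 and 0.37 on the log2 scale, and without that mouse the fitted changes were 5.54 and 1.65. Their calls were lost in 7 and 13 of 15 fits with a mouse left out. In S135 and S151 ENSMUSG00000020427 went from 72.6 ± 43.4 CPM (SD, n = 6) to 17.9 ± 9.31 CPM (SD, n = 6), a log2 fold change of -1.83 ± 0.35 (SE, adjusted p = 0.0031). ENSMUSG00000032315 went from 24.5 ± 16.4 CPM (SD, n = 6) to 6.71 ± 3.17 CPM (SD, n = 6), a log2 fold change of -1.69 ± 0.48 (SE, adjusted p = 0.0313), with the call lost in 7 of those 15 fits. Within batches 79 genes were called in S135 and 774 in S151. The total was 1178 without bleomycin control mouse 148 and 1213 without mouse 225.

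The 2 compartments shared much of the response. Among 17038 genes tested in both, 432 were called higher in both, against 51.3 for independent lists, and 267 lower in both, against 33.5. The lists come from the same mice and are not independent. No gene was called in opposite directions, and 94.9% of the genes raised in epithelium had a positive log2 fold change in whole lung. The test of the difference itself called 29 of 17956 genes, 20 with a log2 fold change after bleomycin that lay higher in epithelium than in whole lung, sign included, and 9 with one that lay lower. Of the 146 batch-limited genes tested, 3 were among these 9 and none was among the 20. In S135 and S151 ENSMUSG00000026669 went from 0.258 ± 0.307 to 5.76 ± 2.92 CPM in epithelium and from 2.01 ± 0.736 to 6.81 ± 4.50 CPM in whole lung (SD, n = 6 each), an interaction of 2.85 ± 0.57 on the log2 scale (SE, adjusted p = 0.049). ENSMUSG00000024672 had no count in epithelial libraries of saline mice and stood at 1.40 ± 0.863 CPM after bleomycin (SD, n = 6), while in whole lung it went from 3.68 ± 1.29 (SD, n = 6) to 11.9 ± 4.26 CPM (SD, n = 6, adjusted p = 0.0283). ENSMUSG00000019987 had the opposite sign, -2.54 ± 0.40 (SE, adjusted p = 0.021), and ENSMUSG00000074336, a batch-limited gene, likewise with -7.22 ± 1.10 (SE, adjusted p = 0.0283). The latter had 8 counts over the epithelial and 3 over the whole lung libraries of saline mice. With a mouse left out, the calls were lost in 11 of 15 fits for ENSMUSG00000026669, 6 for ENSMUSG00000024672 and ENSMUSG00000074336 and 3 for ENSMUSG00000019987. Epithelium-depleted genes had median interactions of 0.26 in S151 and 0.19 in S135, which passed camera (adjusted p = 0.000569 and 0.0426) but not with an estimated correlation (adjusted p = 0.876 and 0.787). Epithelium-enriched genes had a median of -0.06 in S151 (camera adjusted p = 7.5e-05, and adjusted p = 0.523 with an estimated correlation). Without the mouse block 9 genes were called, and 16 without batch S061. The count was 8 without saline mouse 207, 12 without bleomycin control mouse 148, 17 without mouse 149, 19 without saline mouse 221 and 51 without bleomycin control mouse 206.

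**Figure D2:**
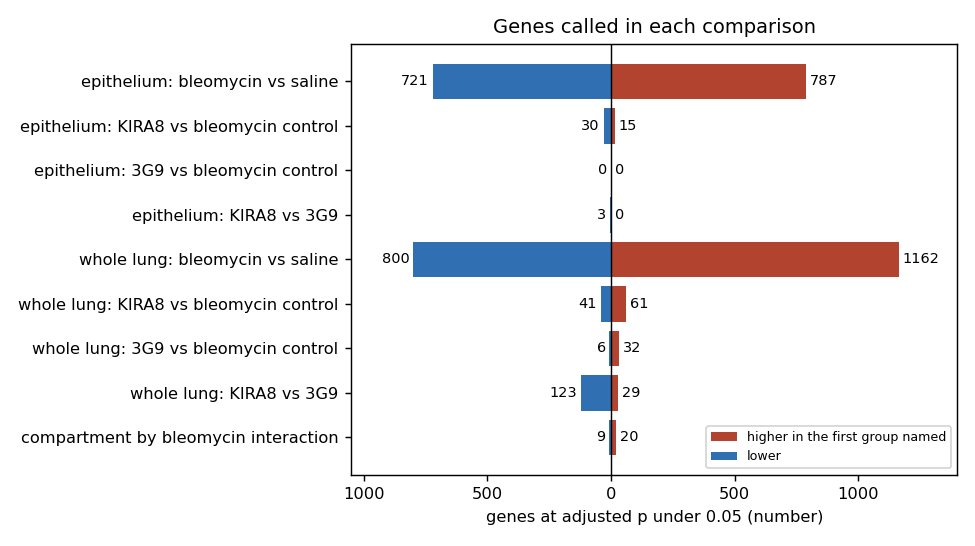
Number of genes with an adjusted p under 0.05 in each comparison, higher (right, red) or lower (left, blue) in the first group named; for the interaction, right counts genes whose log2 fold change after bleomycin, sign included, lies higher in epithelium. Bleomycin against saline calls 1508 genes in epithelium and 1962 in whole lung, and the treatments call from 0 to 152.

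KIRA8 against bleomycin control asked what inhibition of IRE1α changed in injured lung. In epithelium, 15 genes were higher and 30 lower in edgeR and 89 higher and 154 lower in DESeq2, while limma voom with sample quality weights called 1494 higher and 772 lower. ENSMUSG00000024529 stood at 6.53 ± 4.41 CPM with KIRA8 (SD, n = 5) and 32.2 ± 22.5 CPM in bleomycin control mice of the same batches (SD, n = 5), a log2 fold change of -2.29 ± 0.32 (SE, adjusted p = 0.000567), with differences of -2.32 in S061 and -2.13 in S135. ENSMUSG00000035678 was lower by -3.09 ± 0.62 on the log2 scale (SE, adjusted p = 0.0298), reached -4.72 without KIRA8 mouse 32 and lost the call in 5 of 14 fits with a mouse left out. ENSMUSG00000069125 was higher by 1.78 ± 0.35 (SE, adjusted p = 0.0266) and ENSMUSG00000030302 by 1.24 ± 0.26 (SE, adjusted p = 0.0395). The rule for named genes required the same sign in both batches, so that agreement adds nothing for them. These 2 calls were lost in 6 and 10 of those fits, and no gene was called higher without bleomycin control 45, without KIRA8 mouse 41 or with the arms compared alone. Epithelium-enriched genes had a median of 0.07 and depleted genes of 0.00172, and neither group passed a set test after adjustment. Within S135 the medians were 0.14 for enriched and -0.12 for depleted genes, which passed camera (adjusted p = 7.5e-05 and 0.0474) but not with an estimated correlation (adjusted p = 0.523 and 0.876). In S061 the batch-limited genes held 10.8% ± 1.76 of epithelial counts with KIRA8 and 7.72% ± 1.48 in control (SD, n = 3 each), and with that share as a term 3 genes were called, against 2 without S061, 134 within S061 and 15 within S135. Leaving out 1 mouse gave counts from 9, without bleomycin control mouse 45, to 89, without mouse 206; the mice whose absence moved the count by over 1.5 times were bleomycin controls 17, 31, 45, 206, 208R and 225 (21, 17, 9, 89, 27 and 29 genes) and KIRA8 mice 20, 41, 154 and 155 (23, 12, 25 and 18 genes).

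In whole lung, 61 genes were higher and 41 lower with KIRA8 in edgeR. DESeq2 called 420 higher and 281 lower, and the balance turned in limma voom with sample quality weights (424 higher, 701 lower) and with the share of batch-limited genes as a term (68 higher, 87 lower). ENSMUSG00000001131 stood at 141 ± 131.4 CPM with KIRA8 (SD, n = 5) and 453 ± 341 CPM in bleomycin control mice of the same batches (SD, n = 5), a log2 fold change of -1.75 ± 0.37 (SE, adjusted p = 0.0418), with differences of -1.79 in S061 and -1.81 in S135. ENSMUSG00000026580 was lower by -1.46 ± 0.27 (SE, adjusted p = 0.0198). ENSMUSG00000021123 stood at 16.6 ± 16.6 CPM against 4.35 ± 3.62 CPM (SD, n = 5 each), a log2 fold change of 1.79 ± 0.41 (SE, adjusted p = 0.0483), and ENSMUSG00000037846 was higher by 1.62 ± 0.33 (SE, adjusted p = 0.0418). With a mouse left out these calls were lost in 10 of 14 fits for ENSMUSG00000001131 and ENSMUSG00000021123, 8 for ENSMUSG00000037846 and 4 for ENSMUSG00000026580. No batch-limited gene was called, and their share of counts in S061 was 8% ± 0.873 with KIRA8 and 8.66% ± 1.19 in control (SD, n = 3 each). The count was 108 within S061 (70 higher, 38 lower), 0 within S135, 3 without S061 and 66 with sex as a term. It was 0 without KIRA8 mouse 32 and 306 without bleomycin control mouse 149, and it also moved by over 1.5 times without bleomycin controls 17, 31, 45, 148, 204 and 208R (16, 20, 5, 26, 39 and 23 genes) or KIRA8 mice 20, 41, 154 and 155 (167, 23, 51 and 52 genes).

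Under KIRA8, most bleomycin-changed genes had fold changes opposite to the bleomycin change, in mice that had no part in defining the groups, though the group test fell short of the threshold. In epithelium, 250 genes raised by bleomycin in S151 (median log2 fold change 2.31) had a median of -0.41 under KIRA8 in the other batches, with 14.8% positive (limma fry, adjusted p = 0.0519), and 59 lowered genes had a median of 0.40, with 81.4% positive (limma fry, adjusted p = 0.0519). The median of these lowered genes was 0.262 without bleomycin control 148 and 0.535 without bleomycin control 149. In whole lung, 558 raised genes (median 1.42 in S151) had a median of -0.48 under KIRA8, with 11.6% positive (limma fry, adjusted p = 0.0519), and 168 lowered genes had a median of 0.35, with 87.5% positive (limma fry, adjusted p = 0.0519). Adjusted over the 8 tests of this kind, none of the 4 passed the threshold. Under camera all 4 passed (largest adjusted p 3.67e-10), and with an estimated correlation none did (adjusted p = 0.173 for 3 and 0.183 for lowered genes of whole lung). The medians kept their sign within each batch: in epithelium -0.48 in S061 and -0.67 in S135 for raised genes and 0.38 and 0.29 for lowered genes, and in whole lung -0.29 and -0.70, and 0.34 and 0.36. Of single members, 1 passed the test in epithelium and none in whole lung.

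**Figure D3:**
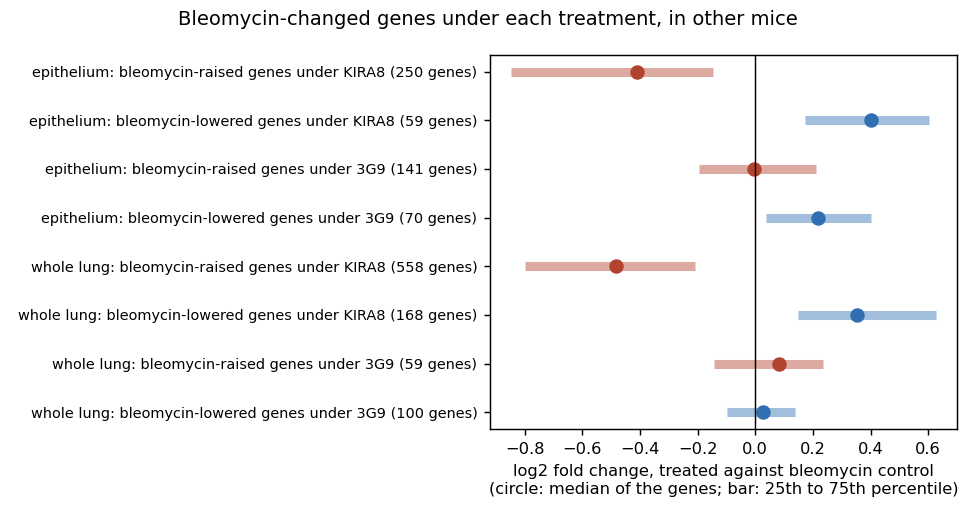
Log2 fold change of treated against bleomycin control mice for genes called higher (red) or lower (blue) after bleomycin in other mice, except that the whole lung 3G9 group of lower genes holds the 100 with the smallest p, of which 18 were called; circles are medians over genes and bars run from the 25th to the 75th percentile. The 4 KIRA8 groups lie opposite to the bleomycin change with medians from -0.48 to 0.40, and the 3G9 groups have medians from -0.00431 to 0.22.

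3G9 against bleomycin control asked what blocking TGFβ activation changed. In epithelium no gene passed in edgeR, with 566 genes at an unadjusted p under 0.05 against 864.6 by chance; DESeq2 called 36 and limma voom 8. The 5 genes with the smallest p all had an adjusted p of 0.45. Among them ENSMUSG00000035042 stood at 7.69 ± 4.68 CPM with 3G9 (SD, n = 4) and 2.30 ± 0.674 CPM in bleomycin control mice of the same batch (SD, n = 4), and ENSMUSG00000029675 at 9.71 ± 3.51 CPM and 65.5 ± 73.3 CPM (SD, n = 4 each). The fitted log2 fold change of the latter went from -2.77 to -1.64 without bleomycin control 208R. Epithelium-depleted genes had a median of -0.08 under 3G9 and enriched genes of 0.02, and neither passed a set test after adjustment.

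In whole lung, 3G9 raised 32 genes and lowered 6. ENSMUSG00000029675 was lower, at 176 ± 52.8 CPM against 711 ± 292 CPM in bleomycin control libraries of the same batch (SD, n = 4 each), a log2 fold change of -1.95 ± 0.33 (SE, adjusted p = 0.0134). ENSMUSG00000061397 was lower by -2.58 ± 0.47 (SE, adjusted p = 0.0187). ENSMUSG00000025877 stood at 38.1 ± 35.5 CPM against 6.55 ± 1.90 CPM in control libraries of the same batch (SD, n = 4 each), a log2 fold change of 2.55 ± 0.47 (SE, adjusted p = 0.0187), and ENSMUSG00000046031 was higher by 2.72 ± 0.54 (SE, adjusted p = 0.0314). With a mouse left out the call was lost in 1 of 13 fits for ENSMUSG00000029675 and in 4 for each of the other 3 genes. The rises leaned on 3G9 mouse 218, whose whole lung column is the one with an unexplained suffix. It stood at -73.1 on the third principal component, against -34.4 to 18.6 for the other mice with 3G9 and -69.7 for bleomycin control 148. The epithelial library of mouse 218, whose column has no suffix, was also the lowest with 3G9 on the third component of epithelium. It stood at -46.1, against -19.4 to -7.83 for the others. Without 3G9 mouse 218, 5 genes were higher and 1 lower, and without 3G9 mouse 228 the count was 211. It was 15, 13, 17 and 77 without bleomycin controls 208R, 206, 204 and 225. No gene passed within S151 alone or with the arms compared alone in the fit.

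Gene groups defined by bleomycin against saline in S135 did not pass under 3G9. In epithelium 141 raised genes had a median of -0.00431 (limma fry, adjusted p = 0.988) and 70 lowered genes a median of 0.22, with 81.4% positive (limma fry, adjusted p = 0.255). The median of these lowered genes was 0.0742 without 3G9 mouse 228 and 0.287 without 3G9 mouse 218. In whole lung 59 raised genes had a median of 0.08 (limma fry, adjusted p = 0.988) and the 100 genes lower after bleomycin with the smallest p, of which 18 had passed in S135, a median of 0.03 (limma fry, adjusted p = 0.988). The lowered genes of epithelium passed camera (adjusted p = 1.14e-07) but not with an estimated correlation (adjusted p = 0.198). The groups differ from those used for KIRA8, and the difference between the treatments on these groups was not tested.

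KIRA8 and 3G9 were given in different batches and were set against each other through the bleomycin controls of each batch. Per the labels those controls received Vehicle in S061 and S135 and Axum8 in S151, so the comparison also rests on these acting alike, which was not tested. In the fits with a mouse left out, only KIRA8 and 3G9 mice were dropped, and none of the bleomycin controls that link them. In epithelium 3 genes were lower with KIRA8 than with 3G9 and none higher. Among them were ENSMUSG00000025511 at -2.13 ± 0.36 on the log2 scale (SE, adjusted p = 0.0218) and ENSMUSG00000023905 at -1.68 ± 0.30 (SE, adjusted p = 0.0416), lost in 3 and 8 of 9 fits with a mouse left out. The count was 0 without 3G9 mouse 218 or 219, 1 without 228, 0 without batch S061, 61 in DESeq2 and 12 in limma voom. In whole lung 29 genes were higher with KIRA8 and 123 lower. ENSMUSG00000072601 was higher by 3.19 ± 0.60 (SE, adjusted p = 0.0139) and ENSMUSG00000030495 by 2.28 ± 0.52 (SE, adjusted p = 0.0448). ENSMUSG00000022126 was lower by -5.61 ± 1.24 (SE, adjusted p = 0.0448) and ENSMUSG00000000982 by -3.63 ± 0.75 (SE, adjusted p = 0.0261). With a mouse left out these 4 calls were lost in 1, 6, 6 and 4 of 9 fits. Epithelium-depleted genes had a median of 0.09, with 56.7% positive, and enriched genes of 0.015, and neither passed a set test after adjustment. Among the 152 called genes, 17 of the 3220 depleted genes were higher and 52 lower, against 3 and 9 of the 1965 enriched genes. The count was 0 without S061 and moved by over 1.5 times without any mouse of either arm: 256, 57, 66, 77 and 63 without KIRA8 mice 20, 32, 41, 154 and 155, and 17, 287, 58 and 576 without 3G9 mice 218, 226R, 219 and 228. Without a batch term 7878 genes were called, which counts the batches as well as the treatments.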

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

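The tests on reads exchanged between libraries, on sex labels, on the depleted genes' share, with each mouse left out of it, and on its ratio to the whole lung share were chosen after the results were seen; the other tests below were set before. The interaction of compartment and bleomycin, with 29 genes, 3 of them batch-limited, was singled out because the same exposure had different effects in the 2 compartments by a test of the difference. The share of batch-limited genes in the whole lung library of saline mouse 146 of S135 was 0.0438%. It stood apart from the other 5 saline whole lung libraries, the nearest at 0.00834%. The batch-limited genes include the female-linked gene. Mouse 146 is labelled female, and this library held 277.9 CPM of that gene, against 58.3 CPM in saline mouse 230, the other female. The sex of the mouse thus enters this share. Of 40 such checks of libraries within groups 1 stood out, and chance gives about 2.

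All 12 libraries of S061 held batch-limited genes, and those of its 2 male-labelled mice held the female-linked gene at 78.6% of its mean in the female-labelled mice. Exchange of reads within the batch is argued against, since the male-linked gene reached at most 0.435% of its male level in a female-labelled library, and a wrong sex label is argued against, since the male-linked gene was at 215.1% of the lowest level of other male libraries or above. RNA of 1 further source in every S061 library could account for it: the 146 genes kept nearly a fixed ratio over the 12 libraries, with a median SD of 0.0702 on the log2 scale against 0.297 in level-matched sets, and 0 of 1000 such sets were as even. The 12 libraries span both compartments, between which the matched genes may differ. Unlike the 146 genes, the matched ones were not picked for a level in every library, so the comparison favours the 146. What the source is was not tested, and no biological explanation was tested. In the whole lung library of mouse 149 the median gene of the group stood at 9.37% of its S061 level (25th to 75th percentile 5.99% to 17.7%). The female-linked gene did not follow, at 0.391 CPM against 121 to 173 CPM in whole lung libraries of S061. Male saline mouse 152 of S135 held 0.347 CPM. Whether mouse 149 shares the source of S061 was not tested, and 1 gene in 1 library cannot settle it.

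KIRA8 libraries of epithelium in S061 held more batch-limited RNA than their controls, which could shift other genes there. If that were the whole cause, genes picked in S061 should lose their direction in S135, where that RNA is near absent. The 100 genes most lowered in S061 had a median of -0.257 in S135, and the 100 most raised a median of 0.171. The difference was -0.428 against a 5th percentile of -0.115 over 10000 random pairs of sets, and 71 and 67 of them kept their sign. Random pairs measure the spread over genes rather than between mice, and S135 held 2 mice per arm, so this test cannot decide the cause. With the share as a term 3 genes were called, which leaves single calls open, and the effect of KIRA8 itself may account for the part shared by both batches.

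The share of counts from genes depleted in epithelial libraries, taken from saline mice of the other batch, was 0.866% ± 0.123 (SD, n = 2) after bleomycin and 0.566% ± 0.112 (SD, n = 3) in saline mice of S135, and 0.513% ± 0.188 (SD, n = 4) and 0.34% ± 0.0731 (SD, n = 3) in S151 (exact two-sided permutation test within batches, p = 0.02). Without bleomycin control 208R, at 0.792%, the difference in S151 fell from 0.173 to 0.0801 points (exact permutation p = 0.02), and over all mice left out in turn the exact permutation p ran from 0.01 to 0.0429. For the summed share, a rise of the same genes in the whole lung is argued against as the whole cause. The log2 ratio of the share in epithelium to that in whole lung of the same mouse was higher after bleomycin by 0.58 in S135 and 0.57 in S151 (exact two-sided permutation test within batches, p = 0.0429). The whole lung share itself changed by 0.05 and -0.02 on the log2 scale. The ratio was not tested with a mouse left out. Single genes may still have risen in whole lung. Of the genes depleted at least 2-fold, 117 of 2629 were called higher and 69 lower there in S151, and 17 and 11 of 3374 in S135. An earlier test of the medians over genes had left a whole lung rise undecided (difference of the compartments, adjusted p = 0.876 and 0.787 with an estimated correlation). RNA of other cells carried over in larger amounts and expression of such genes by injured epithelial cells cannot be told apart, since both raise this share and no test here separates them.

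Chance as the reason for a count was tested with other splits of the same mice within batches. It can be excluded at the 5% level for bleomycin against saline in epithelium (1508 genes, highest other split 421, 1 of 100 splits as large) and whole lung (1962, highest other 386, 1 of 100), for KIRA8 in epithelium (45, highest other 10, 1 of 100) and whole lung (102, highest other 23, 1 of 100), for the compartments in saline mice (8565, highest other 0, 1 of 32) and for the interaction (29, highest other 17, 1 of 30). In whole lung, 3G9 called 38 genes and 3 of 70 splits were as large, which excludes chance narrowly at the same level. The highest other split called 416, and no gene passed within S151 alone or with the arms compared alone. For KIRA8 against 3G9, 3 of 100 splits were as large in epithelium (3 genes, highest other 614) and in whole lung (152 genes, highest other 933). Those splits exchanged each treatment only with the bleomycin controls of its batch. They test whether either treatment differs from its controls, so they cannot decide on chance for a difference between the treatments. What sets apart the splits with the highest counts was not tested. For 3G9 in epithelium the splits say nothing on chance, which cannot be excluded: with 0 genes in edgeR every split is as large by construction (70 of 70, highest other 628), beside 566 genes at an unadjusted p under 0.05, 36 in DESeq2 and 8 in limma voom.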

How the results depend on the processing

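Tests without batch S061, within a batch for the gene sets, and with the share of batch-limited genes as a term were chosen after the results were seen. Bleomycin against saline in epithelium called 1508 genes, 2532 in limma voom, 455 with no batch term, 213 within S135 and 321 within S151, and 1035 to 1859 with a mouse left out. In whole lung it called 1962, 2975 in DESeq2, 3007 in voom, 704 with no batch term, 79 within S135, 774 within S151 and 1178 (without bleomycin control 148; 1213 without 225) to 2115.

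KIRA8 in epithelium called 45 genes, 243 in DESeq2, 2266 in voom (1494 higher, 772 lower), 0 with no batch term in edgeR, 2 without S061, 3 with the share term, 9 with the arms compared alone, 134 within S061, 15 within S135 and 9 to 89 with a mouse left out, moved by bleomycin controls 17, 31, 45, 206, 208R and 225 and KIRA8 mice 20, 41, 154 and 155. In whole lung it called 102, 701 in DESeq2, 1125 in voom (424 higher, 701 lower), 54 with no filter, 0 with no batch term and 66 with sex. It called 3 without S061, 155 with the share term, 22 with the arms compared alone, 108 within S061 and 0 within S135. With a mouse left out the count ran from 0 to 306, moved by bleomycin controls 17, 31, 45, 148, 149, 204 and 208R and KIRA8 mice 20, 32, 41, 154 and 155.

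3G9 in epithelium called 0 genes in edgeR (566 at an unadjusted p under 0.05), 36 in DESeq2, 8 in voom and 0 to 1 with a mouse left out (1 without bleomycin control 148). In whole lung it called 38, 230 in DESeq2, 348 in voom, 1 with no batch term, 19 without S061, 0 with the arms compared alone, 0 within S151 and 6 to 211, moved by bleomycin controls 204, 206, 208R and 225 and 3G9 mice 218 and 228. KIRA8 against 3G9 called 3 in epithelium, 61 in DESeq2, 12 in voom, 5905 with no batch term, 0 without S061, 1 with the share term and 0 to 3, moved by 3G9 mice 218, 219 and 228. In whole lung it called 152, 871 in DESeq2, 1897 in voom, 69 with no filter, 241 with the stricter filter and 7878 with no batch term. It called 89 with sex, 0 without S061 and 274 with the share term. With a mouse left out the count ran from 17 to 576, moved by KIRA8 mice 20, 32, 41, 154 and 155 and 3G9 mice 218, 219, 226R and 228. In both compartments the bleomycin controls were not left out of KIRA8 against 3G9.

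The interaction called 29 genes, 185 in DESeq2, 85 with no filter, 9 without the mouse block, 55 with the mouse as a random block in voom, 16 without S061 and 8 to 51, moved by bleomycin controls 148, 149 and 206 and saline mice 207 and 221. The compartments in saline mice called 8565 genes, 8655 without the mouse block and 7493 to 8469 with a mouse left out.

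Gene sets under KIRA8 kept their sign throughout, and calls below are at an unadjusted limma fry p under 0.05, which in epithelium S061 alone passed (-0.477 for raised and 0.378 for lowered genes) and the other single batches missed. In epithelium S135 alone gave -0.669 for raised and 0.293 for lowered genes, with ranges of -0.502 to -0.339 and 0.262 to 0.535 with a mouse left out, the second losing its call without bleomycin control 148. In whole lung S061 and S135 alone gave -0.289 and -0.704 for raised and 0.34 and 0.363 for lowered genes. With a mouse left out they ran from -0.629 to -0.33, the call ending without bleomycin control 31 or KIRA8 mice 32, 154 or 155, and from 0.265 to 0.456, the call ending without bleomycin controls 17, 31 or 148 or KIRA8 mice 32 or 154. Under 3G9 raised genes of epithelium turned to 0.00968 with 200 genes and ran from -0.0535 to 0.0573 with a mouse left out, and lowered genes had 0.219 with limma camera and ran from 0.0742 to 0.287. In whole lung they ran from -0.0919 to 0.144 and from -0.151 to 0.137. Of 846 values over 37 named genes in 38 pairs of gene and comparison, 257 kept their sign but lost the call, 152 of them among 474 with a mouse left out; most affected were ENSMUSG00000023905 (8 of 9), ENSMUSG00000066071 (13 of 15) and ENSMUSG00000026669 (11 of 15), and under KIRA8 ENSMUSG00000030302, ENSMUSG00000021123 and ENSMUSG00000001131 (10 of 14 each). In epithelium ENSMUSG00000019122 turned to -0.0462 under 3G9 with no batch term.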

Other observations

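The test of cell cycle marker pairs was set before its result was seen. Marker pairs hold a gene that is higher in a phase than its partner in dividing mouse cells, and each library was scored by the percent of pairs in which the phase gene was the higher. After bleomycin the G2/M score of epithelium rose from 36.8 ± 0.695 (SD, n = 3) to 39.7 ± 0.751 (SD, n = 2) in S135 and from 40.6 ± 0.0685 (SD, n = 3) to 44.8 ± 0.932 (SD, n = 4) in S151. In whole lung it rose from 37.5 ± 0.112 to 38.4 ± 1.31 in S135 and from 40.2 ± 0.151 to 42.5 ± 0.280 in S151. The G1 score fell in epithelium from 66.2 ± 0.837 to 62.1 ± 0.376 in S135 and from 63.1 ± 0.246 to 58.1 ± 0.689 in S151. The S score fell as well, in whole lung from 45.0 ± 0.265 to 44.5 ± 0.834 and from 46.1 ± 0.398 to 44.3 ± 0.217.

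More cells in S or G2/M phase of whole lung after bleomycin is a hypothesis that these scores leave open. It needed both scores to rise, and the S score fell while the G2/M score rose, with the same exact two-sided permutation p within batches for both (adjusted over 6 tests 0.00857). In epithelium the adjusted p was 0.00429 for each phase. The pairs were trained on other cells, and a change in the cells that make up the tissue may move the scores without any change in division.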
